A study of Arabidopsis thaliana with 12 samples.

How the data were processed

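Expression was measured in 12 samples of total RNA from Arabidopsis thaliana, 6 titled WT and 6 titled prors1, all described as kept in the dark overnight. The deposited values are intensities on a linear scale, 1 column per sample. The values themselves show a floor at exactly 0 and a ceiling at 100. The scanner, background correction and scaling the authors used are not given in the sources used here. The unit of the scale and what it is relative to stay unknown. All 12 columns were matched to samples by their identifiers, and 0 columns were left over.

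Groups and replicate numbers were read from the titles. Choices of test, samples, alternatives, gene lists and naming rule were made before the data were examined, together with 2 conditional rules. The first was to quantile normalize if the column medians differed by more than 0.1 on the log2 scale, and they differed by 1.22. The second was to average 2 columns of a group that differ only as duplicate spots do. Columns 1 and 2, 3 and 4, and 5 and 6 correlated across probes at 0.902 to 0.915 in WT and 0.951 to 0.961 in prors1, against 0.840 to 0.878 and 0.881 to 0.895 for other columns of the same group. Their median absolute difference was 0.214 to 0.227 on the log2 scale in WT and 0.134 to 0.150 in prors1, against 0.346 to 0.421 and 0.348 to 0.396. Each pair was therefore counted as 1 array. Probes are not independent replicates, and these correlations describe the columns alone.

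Values of 0 were treated as missing and the rest were log2 transformed, quantile normalized over the 12 columns with limma 3.58.1 (R 4.3.3) and averaged per array. Probes with at least 4 of 6 values above 0 in each group were tested, 2908 of 3439. A linear model with group as its only term was fitted with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Log2 folds are prors1 over WT, with the moderated standard error. Levels are given as mean ± SD of the deposited intensity over the 3 arrays, a probe at 0 included. An exact rank test was not used per probe, because with 3 arrays against 3 it cannot go below p = 0.1.

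Probes were named through the platform annotation dated 2016, with symbols updated through the TAIR10.1 gene table. Of the 3439 probes, 692 had 1 gene symbol, 870 had several and 1877 had none listed. Of the 692, 690 matched the gene table, and a probe with several symbols was not used for any gene. Where a gene had more than 1 such probe, the brightest was used. No genome build is named for the probes, so coordinates are left out. Named are the 12 largest rises and the 12 largest falls among genes past the threshold, and in each list with at least 5 tested members the 3 with the smallest unadjusted p. Tested members of shorter fixed lists are given as the result of their list, and 5 further list members past the test were named after their values were seen.

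The 20 gene lists fixed beforehand hold 387 genes, of which 15 were tested. Because so few were measured, 7 further lists were written after the annotation had been read and before any fold was computed. Lists with at least 5 tested members were tested with camera on the moderated statistics with a preset correlation of 0.01, adjusted over 7 lists. Camera with an estimated correlation and fry were run on members measured on all arrays. Alternatives covered the normalization, the filters on dim and missing values, a pseudocount of 0.0595 and an offset of 50. They also covered the array number as a block, the averaging of columns, the test, array weights and the omission of each column. Added later were the 6 columns as separate samples, the omission of each array, and removal of a running median along the probe numbers with 50 numbers on either side.

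The procedure was tested on simulated data for this comparison, built from the means, spread and missing values of the 2908 probes. Of 200 probes given a change, 1 of 67 was called at 1.5-fold (1.49%), 5 of 67 at 2-fold (7.46%) and 35 of 66 at 4-fold (53.0%). The median fitted log2 sizes were 0.59, 0.99 and 1.99. None of the unchanged probes was called (0), nor any in a simulation without change (0). A simulated list of 25 probes shifted 2-fold had a camera p of 8.76e-21, and 2 of 100 random lists had p under 0.05. Noise was drawn independently per probe, whereas deviations of neighbouring probe numbers in the data correlated at 0.167 to 0.584. Column noise was added to a spread between arrays that already held it, so the simulated spread was wider. The simulation changed 200 probes, against 764 called in the data, so its shares and false calls need not carry over.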

Results

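The series compared Arabidopsis thaliana of the Columbia accession with the prors1 mutant after a night in darkness. Per the labels, prors1 lacks prolyl-tRNA synthetase, the enzyme that loads proline onto its transfer RNA. The comparison asks how transcript levels differ between this mutant and WT when no light reaches the plants. PRORS1 stood in the fixed list of organelle aminoacyl-tRNA synthetases, and how much of its activity remains in prors1 was not measured here. Total RNA was measured on a single-channel array with 3439 probes. The 12 columns of values comprised 6 titled WT and 6 titled prors1. The source label of all 12 samples describes WT, so the groups rest on the titles. PRORS1 was named on 0 probes, and the level of the mutated gene, which would check the titles, was not analysed here. Within each group columns 1 and 2, 3 and 4, and 5 and 6 behaved as 2 readings of 1 array and were averaged, which left 3 arrays per group. The labels do not say that the arrays carry RNA from separate plants, so p-values measure only the spread between these arrays, which may be technical.

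Total intensity per column ran from 2312 to 2840 in WT and from 2632 to 3456 in prors1. The median of the values above 0 lay between 0.224 and 0.289 in WT and between 0.407 and 0.520 in prors1. Between 423 and 519 probes per WT column, and between 412 and 474 per prors1 column, were listed at 0. The scale ended at 100, which 1 to 3 probes per WT column and 0 to 2 per prors1 column reached. The number of arrays limits the precision of every value below.

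Among genes with a probe of their own, AT4G13680, which encodes a protein of unknown function, showed the largest rise in prors1 with quantile normalization. Its WT level lay near the floor, and with a pseudocount its log2 fold (2.85) was smaller than that of AT2G46220 (3.01). The log2 fold of AT4G13680 with quantile normalization was 4.79 ± 0.64 (SE, 3 arrays per group, limma adjusted p = 0.00408), from an intensity of 0.0176 ± 0.0081 to 0.802 ± 0.15 (SD). AT2G46220 rose 8.55-fold (log2 fold 3.10 ± 0.29), from 0.910 to 8.66. AT4G19900, a member of a glycosyltransferase family, rose 6.59-fold, and AT4G17070, a peptidyl-prolyl isomerase family protein, rose 5.54-fold. AT1G16080 and AT2G40980 rose by 2.62 ± 0.28 and 2.36 ± 0.36 on the log2 scale. AT1G44830, a transcription factor of the ERF family, rose by 2.32 ± 0.39, and the chromatin remodelling gene chr31 (AT1G05490) by 2.28 ± 0.59. AT1G35340, related to the Lon protease family, and AT3G16310, a nucleoporin-like protein, rose by 2.27 and 2.26. AT3G50350 and AT1G07040 had log2 folds of 3.50 ± 0.88 and 3.31 ± 0.999 from WT intensities of 0.0453 and 0.0377.

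The largest fall was that of AT3G49740, a pentatricopeptide repeat (PPR) protein gene of the family that processes organelle RNA. It fell by 4.47 ± 0.44 on the log2 scale (limma adjusted p = 0.00281), from an intensity of 1.35 ± 0.37 (SD, n = 3) to 0.0791 ± 0.074, and was listed at 0 on prors1 array 2, which the intensities include and the fold leaves out. With a pseudocount in place of the 0 its log2 fold was -3.93. AT5G05330, which encodes an HMG-box protein, fell by 3.32 ± 0.46. AT5G17630, the plastid xylulose 5-phosphate translocator, fell by 2.43 ± 0.36. AT4G24160, the plant homologue of the lipid droplet regulator CGI-58, fell by 1.78 ± 0.46. The fibrillin gene AT5G19940 (FBN6) fell by 1.57 ± 0.28. AT3G53580, diaminopimelate epimerase of lysine synthesis, fell 2.63-fold. AT1G44920, AT3G47100, AT1G51080, AT1G01500, AT3G16760 and AT4G15840 fell by 1.43 to 1.93. These falls are relative to the other probes: AT1G44920, with a log2 fold of -1.93, read 0.0772 ± 0.013 in WT and 0.0732 ± 0.0091 in prors1.

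Direction was kept for these 24 genes under every scaling tried, with as-deposited log2 folds of 2.41 to 6.14 for the rises and of -3.55 to -0.25 for the falls. None of these scalings takes off a constant background of 0.191 to 0.244 per array, which stays open in part below. The prors1 intensities of AT1G35340 (0.250) and AT1G07040 (0.303) lay near that constant, and their WT intensities (0.0323 and 0.0377) far under it. Folds of single genes with the constant were not computed. Of the 12 falls, 4 were called on the values as deposited, those of AT3G49740, AT5G05330, AT5G17630 and AT3G16760, while all 12 rises were. Median scaling lowered the log2 folds of AT2G46220, AT4G19900 and AT4G17070 to 2.32, 2.06 and 1.51, and cyclic loess brought that of AT1G44920 to -1.29. With the pseudocount, which shrinks the folds of dim probes, AT4G13680, AT1G07040, AT2G40980 and AT1G35340 were at 2.85, 1.23, 1.54 and 1.07, and AT5G05330, AT5G17630, AT1G44920 and AT4G24160 at -2.20, -1.50, -0.74 and -1.17, all still called. Leaving out 1 array at a time left 19 of the 24 calls in place. AT3G50350 lost its call without prors1 array 1, 2 or 3 (adjusted p = 0.0818, 0.0628 and 0.0568), and AT1G07040 without WT array 2 (0.0688) or prors1 array 1, 2 or 3 (0.106, 0.117 and 0.0924). The call of chr31 ended without WT array 1 (0.0521) or prors1 array 1, 2 or 3 (0.0669, 0.0824 and 0.0717). That of AT4G24160 ended without WT array 2 or 3 (0.0635 and 0.0727) or prors1 array 1 or 2 (0.0582 and 0.0650), and that of AT1G51080 without WT array 3 (0.0532) or prors1 array 2 (0.0571). Without WT array 1 or 2 the log2 folds of AT1G07040 and AT3G50350 were 2.03 and 2.33, and without WT array 3 that of chr31 was 1.54.

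**Figure D1:**
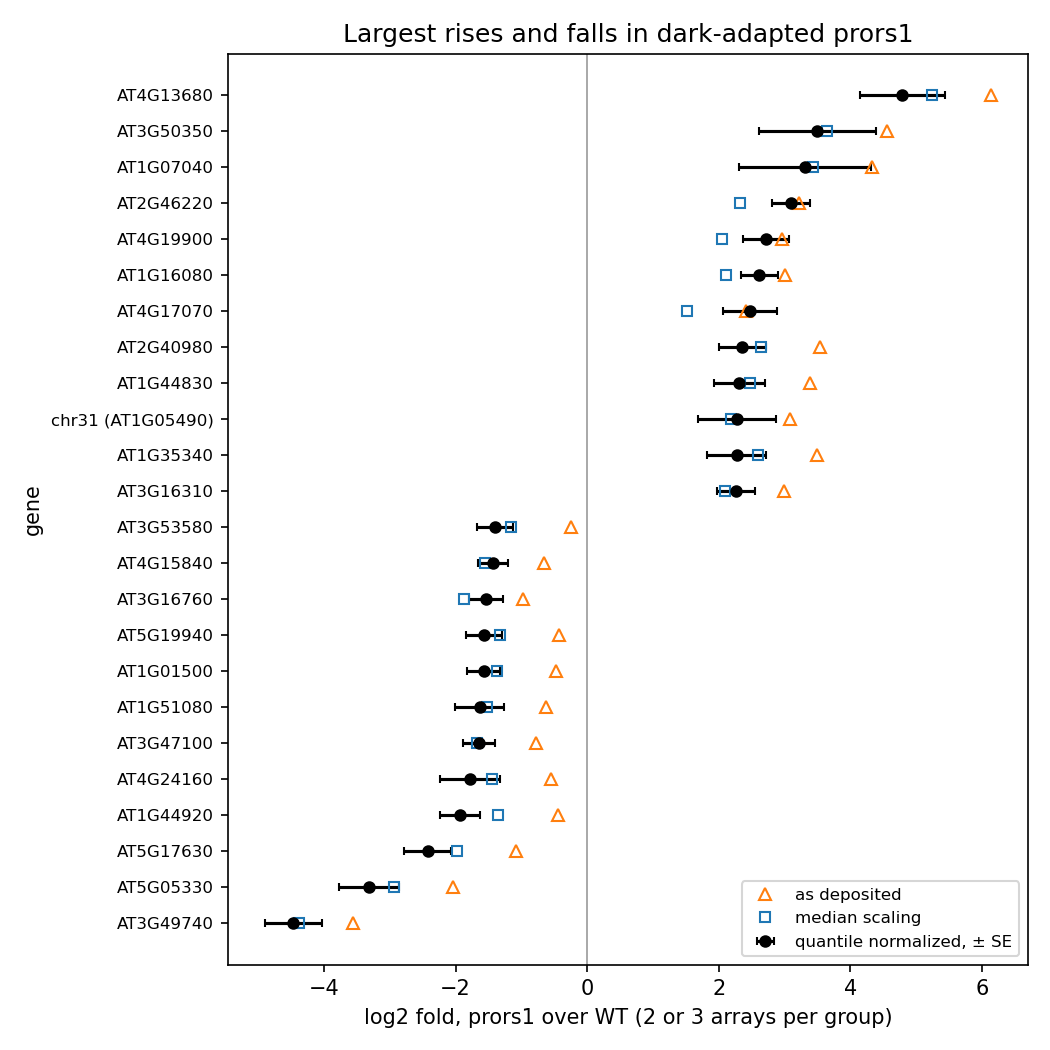
Log2 fold of prors1 over WT for the 12 genes with the largest rise and the 12 with the largest fall, with filled points for quantile-normalized values (bars, SE; 3 arrays per group, but 2 prors1 arrays for AT3G49740) and open symbols for values as deposited and after median scaling. The 24 genes keep their side of 0 in all 3 sets of values, and as deposited the falls lie closer to 0, from -3.55 to -0.25.

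Over all probes, 764 of the 2908 tested (26.3%) changed between prors1 and WT at a limma adjusted p under 0.05, 372 higher and 392 lower. Of these, 297 were higher and 264 lower by at least 2-fold, and 1205 probes had an unadjusted p under 0.05. Among the 581 tested probes that name 1 gene, 84 rose and 72 fell. As deposited, without normalization, the median log2 fold of all probes was 0.77 and 1332 probes were called, 1250 higher (93.8%) and 82 lower. This shift was not common to all probes: the median was 1.07 in the third dimmest of 8 brightness classes and 0.05 in the brightest. Each change given here is relative to the other probes after quantile normalization, which moved probes by different amounts. Median scaling moved the median fold to -0.13, and scaling on genes outside the photosynthesis lists moved it to -0.12. The count fell to 486 without WT array 1, 446 without WT array 3, 465 without prors1 array 1 and 393 without prors1 array 2. The calls lower in prors1 then numbered 225, 180, 236 and 195, and those higher 229 and 198 without prors1 array 1 and 2.

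The calls of photosynthesis genes in prors1 depended on the scaling. With quantile normalization PSBW, a small subunit of photosystem II, rose by 1.71 ± 0.22 on the log2 scale (limma adjusted p = 0.00397), from an intensity of 11.4 ± 0.31 (SD) to 33.2 ± 8.8. PRK, the phosphoribulokinase of the Calvin-Benson cycle, fell by 0.75 ± 0.23, with intensities of 1.13 ± 0.039 and 0.919 ± 0.13. PSBY of photosystem II (-0.23 ± 0.22), PSAN of photosystem I (-0.43 ± 0.23) and the light-harvesting gene LHB1B2 (-0.45 ± 0.33) did not pass the test, and PSBY had the opposite sign as deposited. Under median scaling these 3 were called lower, at -0.90, -1.14 and -1.78 (adjusted p = 0.0251, 0.0189 and 0.0119), and so was PRK at -1.20 (adjusted p = 0.00805). As deposited the folds of the 3 were 0.0042, -0.24 and -0.88, and neither they nor PRK were called. Median scaling moves every probe of a column alike, while the as-deposited median fold was 0.05 in the brightest of 8 classes. It can therefore lower bright probes too far. Quantile normalization can misplace bright probes as well. It gives all columns the same distribution, while the share of signal in the brightest probes differed between the groups (below). Scaling on genes outside the photosynthesis lists called the same 4 lower (-0.89, -1.14, -1.77 and -1.19). It uses every tested probe except the few in those lists, so it nearly repeats median scaling and adds no separate support. Over the 4 tested members of the photosystem, antenna and electron transport lists, 1 was higher and 3 were not past the test, and 1 passed adjusted over the list alone, while under each of these 2 scalings 0 were higher and 3 lower. Their median fold was -0.33 and their mean 0.15, and the set test gave p = 0.535 (p = 0.945 with an estimated correlation). The set's shift relative to all probes was 0.16 and turned to -0.73 as deposited, under median scaling and under scaling on genes outside the photosynthesis lists, where the set test did not pass either. The call of PSBW ended under median scaling (log2 fold 0.61, adjusted p = 0.128) and under scaling on genes outside the photosynthesis lists (0.62, adjusted p = 0.120). That of PRK ended without any 1 array other than WT array 2 (adjusted p = 0.0810 to 0.126), on the values as deposited (0.359) and under cyclic loess (0.0988).

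Of the plastid ribosomal proteins encoded in the nucleus, 0 of 5 tested members passed the test with quantile normalization, also adjusted over the list alone. PRPL5 (AT4G01310) had a log2 fold of -0.61 ± 0.29 from 3 WT and 2 prors1 arrays and PRPL17 (AT3G54210) of -0.41 ± 0.24, and both signs turned as deposited (0.29 and 0.34). Prors1 array 2, where PRPL5 was listed at 0, is left out of its folds; with it the intensities of PRPL5 were 0.285 ± 0.037 in WT and 0.232 ± 0.20 in prors1 (SD), and its fold with a pseudocount was -1.34 (adjusted p = 0.0899). PRPS10 (AT3G13120) had 0.25 ± 0.47 and was called higher as deposited (1.49, adjusted p = 0.0472). PRPL29 (AT5G65220) had -0.07 ± 0.23 and PRPL34 (AT1G29070) -0.01 ± 0.67, with the sign of PRPL29 turned as deposited and under cyclic loess and that of PRPL34 under each of the 4 other scalings. The set test of the list gave an adjusted p of 0.958 over 7 lists (0.950 with an estimated correlation). Of the chlorophyll synthesis genes, CHLM had -0.25 ± 0.23 and AT1G74470, the geranylgeranyl reductase, -0.02 ± 0.24, with the opposite sign as deposited for both and under cyclic loess for AT1G74470. The redox proteins NTRC (0.24 ± 0.25, but called higher as deposited at 1.14, adjusted p = 0.00935) and AT3G52960, a peroxiredoxin (-0.16 ± 0.29, and 0.76 as deposited), did not pass either. AT4G02580, a subunit of mitochondrial complex I, had the large fold of -3.57 ± 1.09 at an adjusted p of 0.0501, from 2 WT and 3 prors1 arrays, and passed adjusted over the list alone, in which it was the single tested member. The fold leaves out WT array 2, listed at 0, with which the intensities were 0.0892 ± 0.11 in WT and 0.0540 ± 0.051 in prors1 (SD), and with a pseudocount it was -0.83 (adjusted p = 0.267). Its adjusted p ran from 0.0517 to 0.203 when 1 array was left out, except without prors1 array 3, where it passed at 0.0136. Of the 387 genes in the 20 lists, 15 were tested, spread over 8 lists. The organelle aminoacyl-tRNA synthetases, the markers of other tissues and the reference genes were among the lists with 0 tested members.

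**Figure D2:**
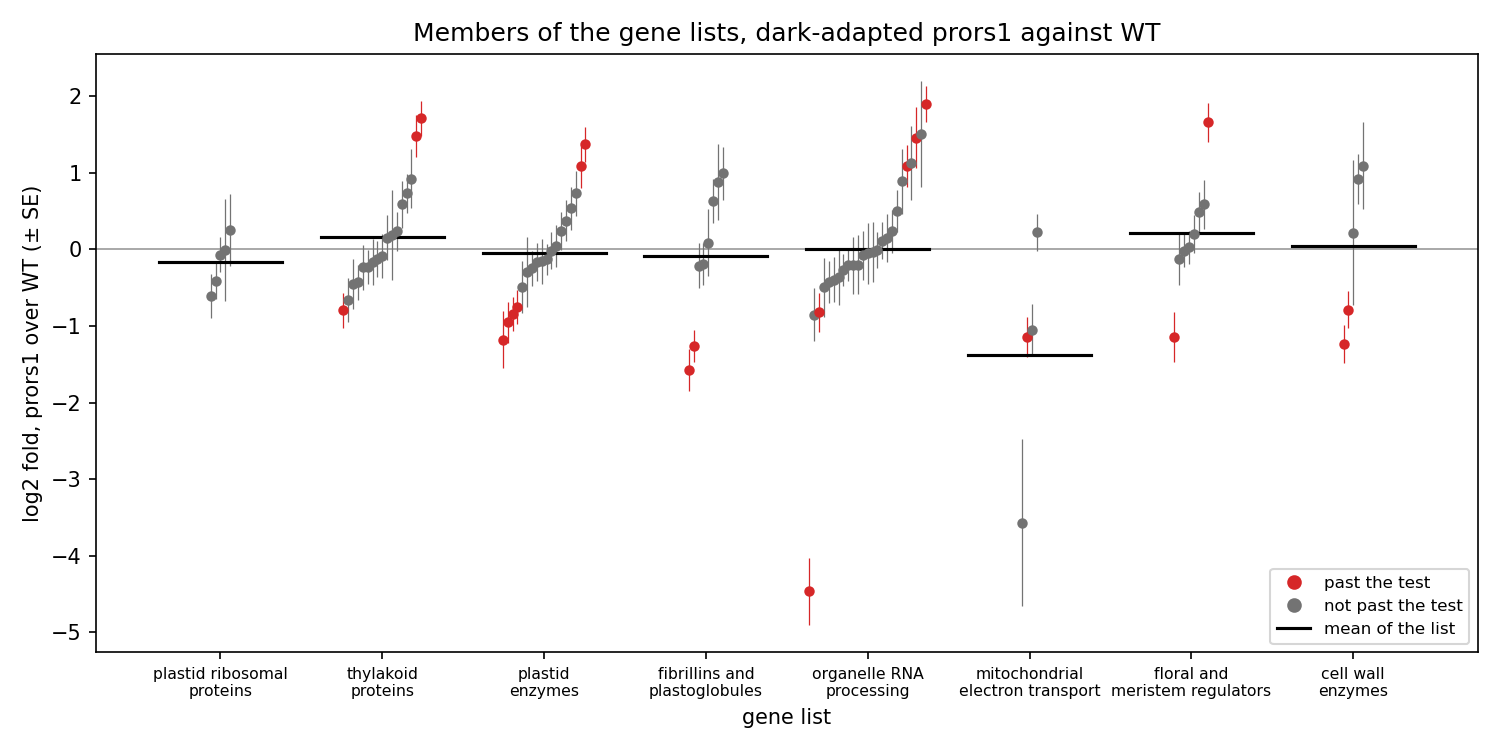
Log2 fold of prors1 over WT (bars, SE; 3 arrays per group, but 2 prors1 arrays for AT4G01310, AT3G49740 and AT5G15280 and 2 WT arrays for AT4G02580 and GH9B8) for each tested member of 8 gene lists, 7 of them described under the additional observations, with members past the test in red and the mean of each list as a line. Members past the test lie on both sides of 0, from -4.47 for AT3G49740 to 1.90 for AT4G04370, and those below 0 that turned sign as deposited are LPA19, SIRB, FATB, PAC and CSLA01.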

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

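The array left-out fits, the 6 columns as separate samples and the probe-number trend were chosen after the data were seen, and the other alternatives before. The count of changed probes, 764 as reported, stayed within 1.5 times under median scaling, cyclic loess, both filters, the pseudocount, the offset, array weights, trend removal, and limma with trend and robust, from 564 to 934. No probe called both there and as reported changed sign under any setting run. It moved to 1332 as deposited (1250 higher, 82 lower), to 1482 with columns 1 and 4, 2 and 5, and 3 and 6 averaged (672 and 810), to 1443 with all 6 columns as separate samples (644 and 799), and to 19 by Welch's test (6 and 13). Counting columns of 1 array as separate raises the degrees of freedom by construction. Averaging columns 1 and 4, 2 and 5, and 3 and 6 puts each array into 2 averages, which narrows the spread between them by construction. The as-deposited count came with a median log2 fold of 0.77, and Welch's test takes each variance from the probe's own arrays alone. Causes beyond these were not tested. Leaving out 1 column or array gave 393 to 756 changed, 198 to 366 higher and 180 to 390 lower, lowest without prors1 array 2 (393, 195 lower), WT array 3 (446, 180 lower), prors1 array 1 (465) and WT array 1 (486), where fewer samples widen the error. With the array number as a block 840 probes were called, 705 of the 764 among them, and as a random block 991 (consensus correlation 0.207). Of the named genes, PRK (0.0517) and PAC (0.0531) were not called with the block, and GH9B16 (0.0329) and AT4G02580 (0.0193) were. Deviations of arrays with the same number correlated at 0.184, 0.080 and 0.231, so the numbers were not taken as pairs, although every array correlated best with its own number, a hint from the data. Single columns gave a stronger hint. Across the groups, columns with the same replicate number correlated at 0.0936 to 0.268, and all other columns at -0.160 to 0.0877. A pairing that the main fit leaves out therefore stays open, and the replicate numbers of single columns were not fitted as a block. Of the 24 largest rises and falls, 15 stayed called with the offset of 50 and 0 by Welch's test. Over the 59 named genes and all settings, 1700 values kept direction and stayed on the same side of the threshold, called or not, 202 kept direction and lost the call, 41 gained one and 43 turned, none of the 43 among the 24. As deposited the folds turned for LPA19 (0.083), SIRB (0.024), CSLA01 (0.29), FATB (0.48), PAC (0.078), PSBY (0.0042), AT4G01310 (0.29), AT3G54210 (0.34), AT5G65220 (0.15), AT1G29070 (1.17), CHLM (0.57), AT1G74470 (0.19) and AT3G52960 (0.76), of which the first 5 were called. AT1G29070 also turned under median scaling (0.27), scaling outside the photosynthesis lists (0.27), cyclic loess (0.20) and trend removal (0.16), AT5G65220 under cyclic loess (0.058), and AT1G74470 under cyclic loess (0.036) and trend removal (0.15). With 1 column or array left out, folds ran from -0.25 to 0.54 for AT3G13120, -0.20 to 0.041 for AT5G65220, -0.79 to 0.50 for AT1G29070, -0.16 to 0.10 for AT1G74470 and -0.37 to 0.056 for AT3G52960. None of the lists had a camera p under 0.05 in any setting, and by fry's directional test the floral regulators alone did, before adjustment over the 7 lists. Fry's mixed test was run on the quantile-normalized values alone. As deposited, under median scaling and under scaling outside the photosynthesis lists, the shift turned for all photosynthesis lists together (-0.73 each), thylakoid proteins (-0.12 each), fibrillins (0.10, 0.11, 0.11) and RNA processing factors (-0.043, -0.038, -0.038). The shift of RNA processing factors also turned under cyclic loess (-0.029), the pseudocount (-0.076), the offset (-0.0029) and array weights (-0.017), that of floral regulators with the offset (-0.00011), and that of cell wall enzymes with the pseudocount (-0.043), the offset (-0.0019) and trend removal (-0.062). With 1 column or array left out shifts ran from -0.078 to 0.020 for plastid enzymes, -0.16 to 0.047 for fibrillins, -0.082 to 0.080 for RNA processing factors and -0.21 to 0.25 for cell wall enzymes. Signal near the floor limits the folds of dim probes, and the exact rank test was not run because 3 arrays against 3 cannot go below 0.1.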

Other observations

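The lists of this part were written after the annotation was read, and tests along the probe numbers, on the ceiling and on a constant background were chosen after the result was seen. Genes for plastid proteins went both ways in prors1, as did all tested probes, of which 26.3% changed (372 higher, 392 lower). The counts of each list below are to be read beside that share, and whether any list differs from it was not tested. AT1G22700 (PYG7), an assembly factor of photosystem I, rose by 1.48 ± 0.27 on the log2 scale (limma adjusted p = 0.00887). LPA19, which assists photosystem II assembly, had a log2 fold of -0.80 ± 0.23 (adjusted p = 0.0381) that turned to 0.08 as deposited. With PSBW, 2 of 17 tested thylakoid proteins were higher and 1 lower, and 3 passed adjusted over the list alone, but 6 were higher and 0 lower as deposited and 1 and 4 under median scaling. Of 18 plastid enzymes 2 were higher and 4 lower, 6 adjusted over the list alone, with 7 and 0 as deposited. Sulfiredoxin (SRX) rose by 1.37 ± 0.23 and the ATP sulfurylase APS4 by 1.08 ± 0.28. SIRB of sirohaem synthesis (-0.84 ± 0.22), the acyl-ACP thioesterase FATB (-1.18 ± 0.37), the Rubisco chaperone BSD2 (AT3G47650, -0.95 ± 0.26) and PRK were called lower, with the sign turned as deposited for SIRB (0.02) and FATB (0.48). FATB lost its call under median scaling (-0.42, adjusted p = 0.276), cyclic loess (-0.32, adjusted p = 0.449) and with a pseudocount (-0.47, adjusted p = 0.187). BSD2 lost it as deposited (-0.54, adjusted p = 0.128) and under cyclic loess (adjusted p = 0.0683). FATB, BSD2, PAC, AT1G79220 and GLDH were named after their values were seen. LPA19 and FATB were called in no fit that left out 1 of the 6 arrays (adjusted p = 0.0598 to 0.110 and 0.0561 to 0.127, with FATB at -0.75 without prors1 array 1), SIRB and BSD2 in 1, that without prors1 array 3 or WT array 2 (elsewhere 0.0643 to 0.0756 and 0.0704 to 0.0949). APS4 was not called without WT array 1 or 3 or prors1 array 2 or 3 (0.0643, 0.0763, 0.0836 and 0.0726). Of 8 fibrillin and plastoglobule genes, FBN2 (AT2G35490) fell by 1.26 ± 0.21 beside FBN6, and AT4G13200 (0.99 ± 0.35, adjusted p = 0.0668) did not pass, but was called without WT array 1 (0.0411) and as deposited (2.02, adjusted p = 0.00296). FBN2 was not called as deposited (-0.33, adjusted p = 0.311), where 3 of the 8 were called higher and 0 lower.

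Among 25 organelle RNA processing factors, 3 were higher and 2 lower, 4 adjusted over the list alone, with 8 and 2 as deposited and 2 and 4 under median scaling. The PPR genes AT4G04370 and AT4G21170 rose by 1.90 ± 0.24 and 1.09 ± 0.28 and the mTERF gene AT1G79220 by 1.46 ± 0.40, while the PPR gene AT3G49740 fell. PAC, needed for chloroplast RNA, had -0.82 ± 0.25 and 0.08 as deposited. AT4G21170 was not called under median scaling (0.80, adjusted p = 0.0538), nor AT1G79220 under cyclic loess (adjusted p = 0.0540). PAC was called in no fit that left out 1 array (adjusted p = 0.0543 to 0.130), and AT1G79220 in 1, that without WT array 2 (elsewhere 0.0533 to 0.101). AT4G21170 was not called without WT array 1 or 2 or prors1 array 1 or 3 (0.0520, 0.0641, 0.0628 and 0.0661). Of 4 mitochondrial electron transport genes, GLDH, the last enzyme of ascorbate synthesis, fell by 1.14 ± 0.26, with the call lost without WT array 3 (-1.08, adjusted p = 0.0548) and as deposited (-0.20, adjusted p = 0.606), and 3 passed adjusted over the list alone. Among 8 floral and meristem regulators the MADS-box gene AGL54 rose by 1.66 ± 0.25 and the auxin response gene IAA31 fell by 1.15 ± 0.33, both past the test adjusted over the list alone, and TCP15 (0.59 ± 0.32) did not pass except as deposited (adjusted p = 0.00981), where 5 of the 8 were called higher and 0 lower. IAA31 was called in 1 fit with an array left out, that without prors1 array 3 (elsewhere 0.0618 to 0.101), and not as deposited (-0.67, adjusted p = 0.0936). Among 5 cell wall enzymes GH9B12, of the endoglucanase family, fell by 1.24 ± 0.25, GH9B16 had 0.92 ± 0.33 (adjusted p = 0.0703, but 0.0306 without prors1 array 1, 0.00218 as deposited at 1.96 and 0.0400 under median scaling), and CSLA01 of the mannan synthase family had -0.79 ± 0.24, turned to 0.29 as deposited, with 3 members past the test over the list alone. GH9B12 was not called as deposited (-0.57, adjusted p = 0.0961), nor CSLA01 under median scaling (-0.61, adjusted p = 0.0909), under cyclic loess (-0.70, adjusted p = 0.0501) or without any 1 array (0.0632 to 0.122). None of the directional set tests passed over the 7 lists (camera adjusted p = 0.958 to 0.977, 0.950 with an estimated correlation), and for the floral list, with 1 member higher and 1 lower, fry gave p = 0.00975 but an adjusted p of 0.0683. Fry's mixed test, which asks whether members change in either direction and does not compare a list with other genes, passed for the 6 added lists tested (adjusted p = 4.71e-07 to 0.00482) and not for the plastid ribosomal proteins (0.808), and it also passed, unadjusted, for all photosynthesis lists together. Median, mean and test differed in sign for thylakoid proteins (median -0.09, mean 0.17, test up), RNA processing factors (median -0.05, mean 0.0043, test up) and cell wall enzymes (median 0.22, mean 0.04, test down). AT4G12270 was listed at 0 in all 6 WT columns and at 0.0878 to 0.352 in the 6 prors1 columns, as 1 of 10 such probes, against 0 probes the other way. It was named after its values were seen, and the constant background weighed below (0.191 to 0.244 per array) is of similar size.

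The 764 changed probes were set against technical explanations. With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05, and 1 of the 10, the real one, reached 764, with 0 in the highest other. The fold depended on brightness as deposited, with medians from 1.07 in the third dimmest of 8 classes to 0.05 in the brightest. With cyclic loess 89.0% of the calls stayed, but this cannot decide on brightness as a cause. The calls were made after quantile normalization, which had already brought the class medians to between -0.37 and 0.07. On the values as deposited 445 of the 764 calls stayed. The 92.3% of calls that stayed with the array number as a block decide nothing on a difference between array pairs. Each number stands once in each group, so the folds of fully measured probes cannot move. Folds of neighbouring probe numbers correlated at 0.0272. This cannot decide on a place effect on the membrane, which could recur at longer distances. Folds 6, 12, 18 and 24 numbers apart correlated at 0.126, 0.127, 0.0960 and 0.0897, and those 5 apart at 0.0950. Other distances up to 24 gave -0.0387 to 0.0425. A place effect therefore stays open. A slow trend along the numbers is argued against by the 94.4% of calls that stayed after its removal. The running median follows slow change alone, so this cannot decide on a repeat every 6 numbers. The genotype stays open beside any difference in RNA, hybridization or exposure that follows the titles, which was not tested.

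Within a group, neighbouring probe numbers deviated together on every array. The correlation was 0.167 to 0.253 on the WT arrays and 0.456 to 0.584 on the prors1 arrays, against at most 0.0739 over 100 shuffles. With the lowest prors1 value at 0.456, the spread may follow the place of the spot, a hypothesis found in these data. No biological explanation was tested.

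The brightest 20 probes held 20.3% to 25.7% of the signal on the prors1 arrays and 33.5% to 36.5% on the WT arrays. The ceiling of the scale as the whole cause is argued against, since the 2 prors1 arrays with no value at the ceiling still stood at least 8.58 percentage points below every WT array (SD between arrays 2.33). A constant on top of every prors1 value would leave no probe at 0. Yet 412 to 474 probes per prors1 column were listed at 0, which argues against that form of a higher background. A higher background on part of the probes, or from before the floor was set, cannot be told apart from the other explanations. A constant added to WT took the difference of the mean shares from 11.3 to 3.13 percentage points. It left the nearest arrays 0.278 apart (SD 2.12). The same constant brought the median log2 folds of the 5 brighter of 8 brightness classes to between -0.16 and 0.10, and those of the 3 dimmest, near the floor, to between -1.16 and -0.22. Folds of single genes were not computed with it, so every rise from a dim WT level given above carries this limit. A longer exposure or more label on the prors1 arrays was not tested, and the genotype stays open.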
